A study of Mus musculus with 11 samples.

How the data were processed

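RNA was measured in primary mouse hippocampal neurons, cells isolated from the hippocampus and grown in culture for 10 days at 20% oxygen. Per the labels, 6 libraries came from cells left at 20% oxygen (control) and 5 from cells placed at 1% oxygen for 4 h (hypoxia) in a hypoxia workstation, and the control cells were from the same isolation as the hypoxic cells. Per the labels' protocols, RNA was extracted with Trizol, polyadenylated RNA was made into libraries with the TruSeq RNA Library Prep Kit v2, which does not mark the strand, and single-end reads of 50 bp were sequenced on a HiSeq2000. The labels do not say whether libraries of one group came from separate isolations or dishes, so every p-value measures the spread between these libraries, which may in part be technical.

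The authors deposited read counts per Ensembl gene ID, 1 table per library, as whole numbers that were not normalized. Per the submitters' processing notes, the tools were FastQC 0.11.5, STAR 2.5.2b, featureCounts, Subread 1.5.1 and DESeq2, and the genome build was mm10; the annotation release, the strand setting and the handling of reads that match several places are not given in the sources used here. Each table held 48709 gene IDs, of which 48349 were matched to a symbol and 15721 had 0 counts in all libraries. The authors also deposited 2 tables of their own comparison, one of 2099 genes higher and one of 1693 genes lower in hypoxia. Per the file headers, these hold log2 fold changes and adjusted p-values, the largest of which was 0.0500, for each listed gene. Their per-library columns hold a normalized signal, which was found by division to be the deposited count over 1 size factor per library.

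How the counting was done affects which genes can be read. Several abundant transcripts with many processed pseudogenes, such as Gapdh, Pgk1, Pgam1, Rps18 and Rpl5, had low counts, so their values may cover only part of their reads and are uncertain. The mitochondrially encoded mRNAs mt-Nd3, mt-Nd4l, mt-Co3, mt-Atp6 and mt-Atp8 were listed at 0 in all libraries and mt-Co2 had 1 count in all, and these were not tested. Hspa1a and Hspa1b are near-identical copies and share reads. Without strand, reads of an antisense gene cannot be told from those of the gene it overlaps, and the ends of mt-Nd5 and mt-Nd6 overlap.

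Group and replicate were taken from the sample titles. The main test was edgeR 4.0.16 (R 4.3.3): genes were filtered with filterByExpr by group, TMM factors were computed, and the quasi-likelihood F test (glmQLFit with robust set to FALSE, glmQLFTest) compared hypoxia with control, 2-sided, with no covariate. Of all counts, 99.9% lay in the 16235 genes tested. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change was its size divided by the square root of the F statistic. Levels are given as CPM, counts scaled to a library size of 1e+06 with TMM-scaled library sizes, as mean ± SD over the 6 control or 5 hypoxia libraries, and fold changes are hypoxia over control.

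A set of 27 gene lists was fixed before the data were examined: HIF targets outside glycolysis, glycolysis and glucose uptake, JmjC histone demethylases, H3K4 methyltransferase complexes, ER chaperones and the unfolded protein response, ATF4 and the integrated stress response, immediate-early genes, glutamatergic synapse, synaptic vesicle release, GABA synthesis, transport and receptors, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs, cholesterol synthesis and uptake, cytosolic heat shock proteins, p53 targets, cell cycle, circadian clock, ribosomal proteins, the interferon response, and markers of excitatory neurons, interneurons, astrocytes, oligodendrocyte lineage cells, microglia, endothelial and mural cells, fibroblasts and meninges, and choroid plexus and ependyma. Each was tested with camera (limma 3.58.1) with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry, which asks whether the genes of a list move at all and does not compare them with other genes. Some lists share members: Aldoc is in the glycolysis and astrocyte lists, and Pdgfra is in the oligodendrocyte and fibroblast lists.

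The genes named in the text were fixed by a rule before the data were examined. It takes the 8 largest increases and the 8 largest decreases among called genes with a mean CPM of at least 5 in the higher group and no overlap between the groups' libraries, leaving out predicted genes, then the 3 called members of each list with the smallest p-value or, where none was called, the most abundant member, and 8 genes whatever their values (Hif1a, Epas1, Kmt2a, Kmt2b, Kmt2c, Kmt2d, Setd1a and Setd1b). Other members are named where a count of genes was small or an example was needed, and these were chosen after their values were seen. Some genes that the rule names are not reported here and were left out of the search for libraries that stand apart, though they remain in all tests and counts. Coordinates are from GENCODE release M21 on GRCm38, the assembly that mm10 denotes.

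The scripts were tested on counts simulated from these libraries' means and sizes for the same comparison and 16235 genes, with 200 genes changed. Of the 67 genes changed by 25%, 64.2% were called, of the 67 changed by 1.5-fold 88.1%, and of the 66 changed by 2-fold 97.0%; 5.68% of the 176 calls were unchanged genes. No libraries were duplicates: over the 15 control and 10 hypoxia pairs, the chi-square statistic per degree of freedom of their counts was at least 2.18 and 2.30, above the value of 1 that sampling alone gives. Single values were compared by exact permutation over the 462 splits of the 11 libraries, 2-sided.

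The alternatives set before the data were examined were RLE, upper-quartile and no scaling factors, no filter on low counts, a filter of CPM above 1 in at least 5 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, libraries thinned to the smallest total, each of the 11 libraries left out in turn, and for the overlap with the authors' tables an adjusted p under 0.01. A GC correction per library in 20 bins of transcript GC content, a covariate for the leading axis of variation within groups, and a fit without control 1, control 2 and hypoxia 5 were added after the data were seen, as were 5 further gene lists described under other observations.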

Results

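Gene expression was measured by RNA sequencing in cultured mouse hippocampal neurons after 4 h at 1% oxygen (hypoxia, 5 libraries) and in neurons kept at 20% oxygen (control, 6 libraries). The series title sets the exposure in work on heart failure, memory and epigenetic regulation. The comparison asks which transcripts differ in these neuron cultures after a short period of low oxygen. Total counts per library ran from 1.66e+07 in control 1 to 3.19e+07 in hypoxia 5, with a mean of 2.71e+07 ± 5.41e+06 in control and 2.63e+07 ± 3.44e+06 in hypoxia (SD, n = 6 and 5), a difference smaller than the spread between libraries (exact permutation p = 0.801).

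After 4 h of low oxygen, 1644 genes were higher and 2078 were lower at an adjusted p under 0.05 among 16235 genes tested with edgeR. Transcripts of HIF target genes, ATF4 target genes, immediate-early genes, JmjC histone demethylases and clock genes were higher as groups. Most genes of glycolysis and glucose uptake and of sterol synthesis were also higher and most measured mitochondrially encoded mRNAs lower. The camera calls of these lists were lost with an estimated correlation between genes (adjusted p = 0.229, 0.249 and 0.249). Some other splits of the libraries also gave these lists camera p-values as small. Each list passed fry, which does not compare it with other genes (adjusted p = 0.00275, 0.00187 and 0.00187). Most differences were small: 1184 of the higher genes and 1085 of the lower genes differed by less than 25%, as the ratio of the higher to the lower group, and 64 genes were higher and 61 lower by at least 2-fold. The higher genes had a median fold change of 1.16 and a median level of 50.1 CPM, and the lower genes a median ratio of control to hypoxia of 1.24 and a median level of 16.4 CPM. The first principal component, with 30.1% of the variance, separated the groups. Higher calls made up 44.2% of all calls.

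The largest increase by the fixed rule was in Adm (ENSMUSG00000030790, chromosome 7, 110627661 to 110629820), which encodes the vasodilator peptide adrenomedullin. Adm rose from 2.63 ± 1.08 CPM in control to 11.2 ± 1.20 CPM in hypoxia, a log2 fold change of 2.06 with an SE of 0.19 (adjusted p = 1.83e-06). Arl4d (chromosome 11, 101665541 to 101667832), a small GTPase of the ARF family, rose 4.15-fold, and the stress-induced transcription factor Atf3 (chromosome 1, 191170296 to 191218039) rose 4.05-fold. The activity-dependent transcription factor Npas4 rose 3.55-fold, hexokinase 2 (Hk2) 3.39-fold, the small Maf protein Maff 3.25-fold, Gadd45g 3.18-fold and Chac1, a glutathione-degrading enzyme, 3.11-fold. Each of these genes was higher in every hypoxia library than in every control library, which the rule required.

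The largest decrease by the same rule was in Txnip (ENSMUSG00000038393, chromosome 3, 96557957 to 96561883), an alpha-arrestin that binds thioredoxin and limits glucose uptake. Txnip fell from 28.3 ± 5.75 to 6.01 ± 1.97 CPM, a log2 fold change of -2.22 with an SE of 0.17 (adjusted p = 2.96e-07). In hypoxia 5 it stood at 9.54 CPM, and in the other hypoxia libraries at 5.05 to 5.27 CPM. The related alpha-arrestin Arrdc4 (chromosome 7, 68736995 to 68749241) also fell, from 56.7 ± 5.69 to 29.3 ± 5.93 CPM. The other large decreases were in Nabp1, a single-stranded DNA binding protein (log2 fold change -1.23), the mitochondrial leucine tRNA gene mt-Tl1 (-1.17), the thioesterase Lypla1 (-0.95), the RNA-binding protein Mex3b (-0.90) and the noncoding genes AW047730 (-0.94) and C78859 (-0.91). As the libraries were made from polyadenylated RNA, the counts of mt-Tl1 need not measure mature tRNA. They may in part come from reads of the genes beside it, which changed less.

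**Figure D1:**
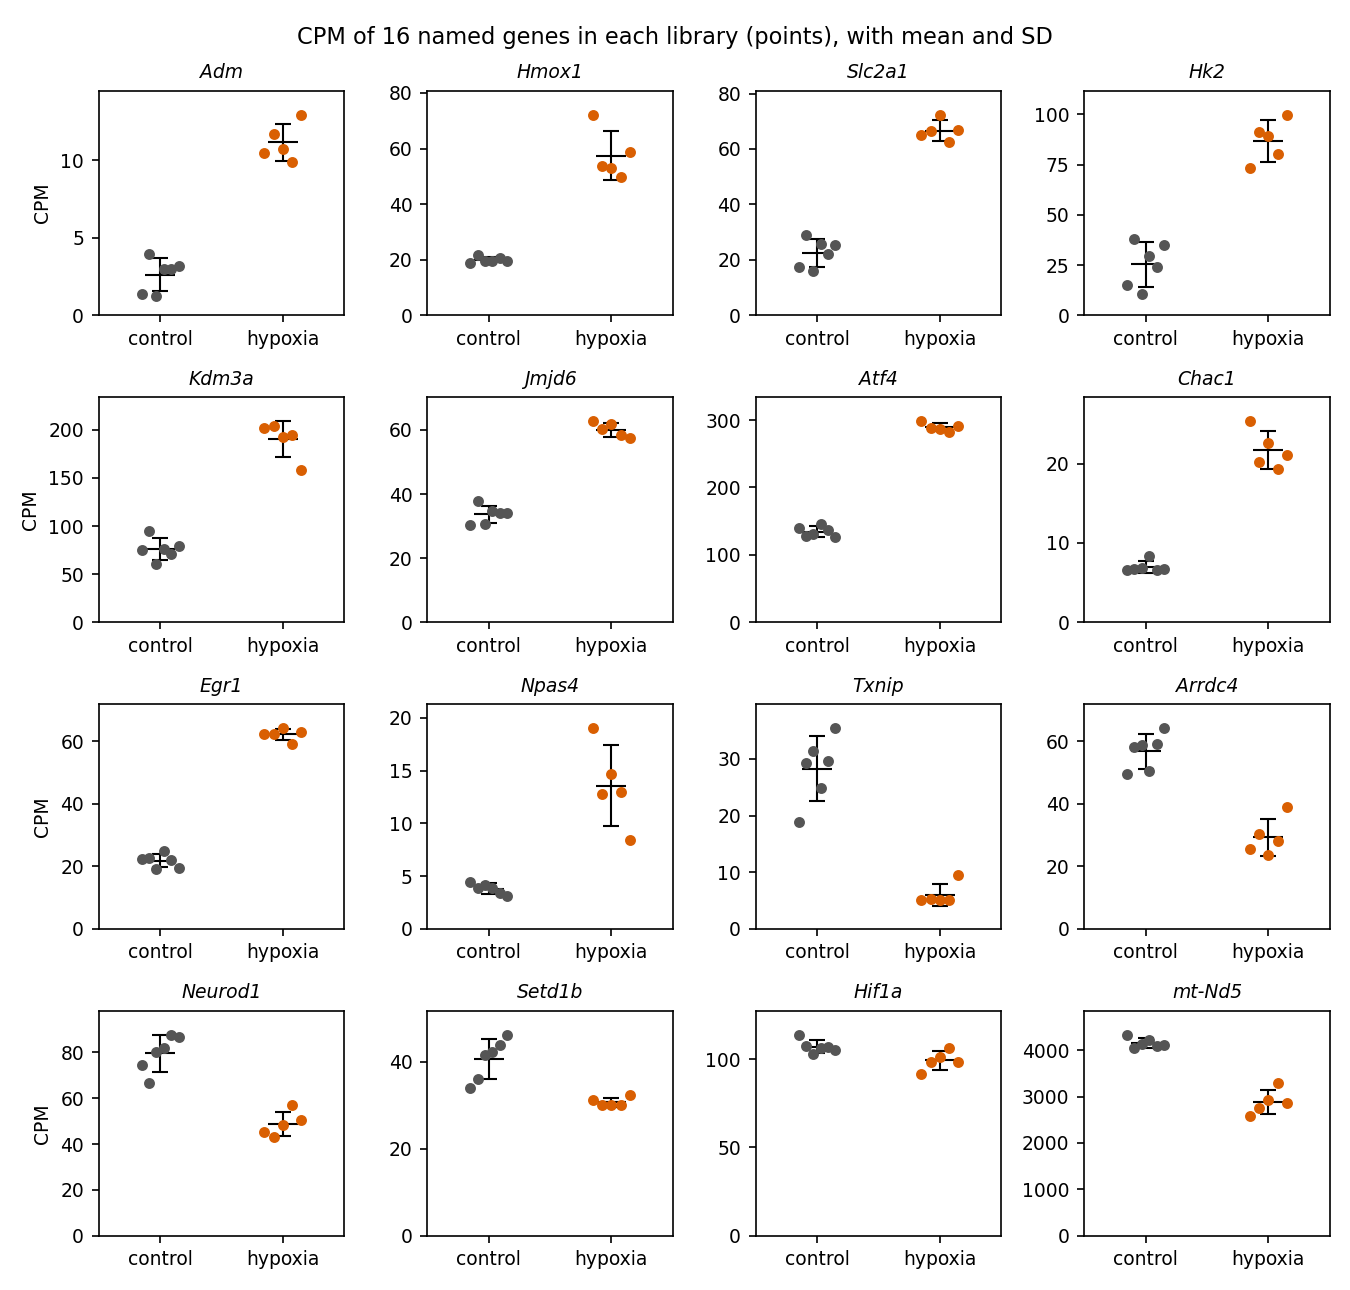
Expression of 16 named genes in each library, in CPM on linear axes from 0, with 6 control (grey) and 5 hypoxia (orange) libraries as points and bars at the mean ± SD. Adm, Kdm3a, Atf4 and Egr1 separate the groups fully, Txnip falls to 6.01 CPM on average with hypoxia 5 at 9.54 CPM, and the Hif1a values of the groups overlap.

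HIF targets outside glycolysis rose as a group. Of 25 members tested, 22 were higher and none lower (24 and 0 when adjusted over the list alone), with a median log2 fold change of 0.67 (camera adjusted p = 2.21e-46, and adjusted p = 0.0125 with an estimated correlation). Hmox1, which encodes heme oxygenase 1, rose from 20.0 ± 1.09 to 57.4 ± 8.86 CPM, the transcription factor Bhlhe40 from 27.7 ± 5.20 to 71.2 ± 2.07 CPM, and the collagen prolyl hydroxylase subunit P4ha1 from 86.2 ± 11.9 to 174 ± 6.44 CPM. Vegfa, the vascular growth factor, rose 2.02-fold and the oxygen sensor Egln3 2.77-fold. Bnip3, Car12 and Car9 did not pass the threshold, with log2 fold changes of 0.33, 0.41 and 0.50. Hif1a, the oxygen-regulated alpha subunit of HIF-1, was at 107 ± 3.61 CPM in control and 99.3 ± 5.17 CPM in hypoxia (adjusted p = 0.0614). Without hypoxia 4 the adjusted p of Hif1a was 0.0316, and over all alternatives it ran from 0.0284 to 0.235. Epas1, which encodes HIF-2 alpha, was at 10.5 ± 1.04 and 10.1 ± 0.635 CPM (adjusted p = 0.688).

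Among 22 genes of glycolysis and glucose uptake, 18 were higher and 1 was lower, the same counts as when adjusted over the list alone, with a median log2 fold change of 0.33. The camera adjusted p was 2.08e-13, and this call was lost with an estimated correlation between genes (adjusted p = 0.229 with an estimated correlation). The glucose transporter Slc2a1 rose from 22.6 ± 5.04 to 66.7 ± 3.67 CPM, Hk2 by 1.76 on the log2 scale (SE 0.22) to 86.7 ± 10.3 CPM, and Pfkfb3, which makes the phosphofructokinase activator fructose 2,6-bisphosphate, from 129 ± 24.4 to 310 ± 2.75 CPM. The lactate exporter Slc16a3 rose 2.09-fold, and lactate dehydrogenase A (Ldha) 1.31-fold. Pfkfb4 was the member that was lower (log2 fold change -0.24), and Pfkp, Aldoc and Pfkm did not pass the threshold. Gapdh, Pgk1 and Pgam1 were higher too, but their low counts make their levels uncertain.

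ATF4 and its targets in amino acid metabolism and stress rose together, with 18 of 23 higher and none lower (21 and 0 when adjusted over the list alone) and a median log2 fold change of 0.45 (camera adjusted p = 2.00e-55, and adjusted p = 0.000218 with an estimated correlation). Atf4 itself (chromosome 15, 80255184 to 80257541) rose from 135 ± 7.95 to 289 ± 5.96 CPM, with the smallest adjusted p of all genes beside Egr1 (7.28e-11). Atf3 rose from 1.39 ± 0.132 to 5.63 ± 0.605 CPM and Chac1 from 6.96 ± 0.714 to 21.7 ± 2.37 CPM. Trib3, a pseudokinase induced by ATF4, rose 3.19-fold, the mitochondrial folate enzyme Mthfd2 1.96-fold, and the cystine transporter subunit Slc7a11 by 0.59 on the log2 scale. The members that did not pass the threshold were Cebpb, Nupr1, Atf5, Phgdh and Slc7a3.

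The list of ER chaperones and unfolded protein response genes did not move as a group (3 higher and 6 lower of 24, the same when adjusted over the list alone, camera adjusted p = 0.735, median log2 fold change -0.05), although its members changed in both directions (fry mixed adjusted p = 9.49e-12). Most lists passed this mixed test, among them H3K4 methyltransferase complexes (4.64e-07), ribosomal proteins (6.42e-07), heat shock genes (2.49e-06) and p53 targets (1.36e-06). Herpud1, which acts in ER-associated degradation, rose from 37.2 ± 1.88 to 64.3 ± 2.58 CPM, and Atf6 and the chaperone Hsp90b1 each rose by less than 25%. Edem1, which directs misfolded glycoproteins to degradation, fell from 39.9 ± 1.42 to 32.7 ± 0.942 CPM, and Ern1, which encodes the ER stress sensor IRE1 alpha, from 15.3 ± 0.966 to 11.5 ± 0.584 CPM. Xbp1, whose mRNA IRE1 alpha splices, Dnajb9, Dnajc3 and Creld2 also fell, with log2 fold changes of -0.32, -0.25, -0.20 and -0.28. The major ER chaperone Hspa5 had a log2 fold change of -0.01.

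Activity-regulated immediate-early genes rose as a group, with 15 of 22 higher and 1 lower (16 and 1 when adjusted over the list alone) and a median log2 fold change of 0.59 (camera adjusted p = 1.94e-32, and adjusted p = 0.00127 with an estimated correlation). Egr1, a zinc finger transcription factor, rose from 21.8 ± 2.08 to 62.2 ± 1.88 CPM, the MAP kinase phosphatase Dusp1 from 6.43 ± 0.548 to 17.4 ± 0.884 CPM, and Jun from 35.6 ± 4.23 to 86.5 ± 3.59 CPM. Fos rose by 1.58 on the log2 scale and the synaptic gene Arc 1.98-fold. Nr4a2 was lower (log2 fold change -0.28), and the neurotrophin gene Bdnf had a log2 fold change of -0.05 and did not pass the threshold.

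JmjC histone demethylases, enzymes that use oxygen to remove histone methylation, were higher for 12 of 19 members and lower for 1 (13 and 1 when adjusted over the list alone), with a median log2 fold change of 0.23 (camera adjusted p = 1.26e-10, and adjusted p = 0.0125 with an estimated correlation). Kdm3a (chromosome 6, 71588972 to 71632990), an H3K9 demethylase, rose from 76.3 ± 11.2 to 191 ± 18.4 CPM, with hypoxia 5 at 159 CPM and the other hypoxia libraries at 193 to 204 CPM. Jmjd6 rose from 33.6 ± 2.78 to 60.1 ± 2.18 CPM, and Kdm5b, an H3K4 demethylase, from 187 ± 8.33 to 262 ± 0.984 CPM. Kdm5a, also an H3K4 demethylase, rose 1.17-fold, and Kdm6a, an H3K27 demethylase, fell (log2 fold change -0.23).

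H3K4 methyltransferase complexes did not move as a group (2 higher and 2 lower of 15, the same when adjusted over the list alone, camera adjusted p = 0.665). The list's median log2 fold change was 0.01 and its mean just below 0. Setd1b (chromosome 5, 123142193 to 123168629), a catalytic subunit, fell from 40.6 ± 4.67 to 30.7 ± 1.04 CPM (adjusted p = 0.000413), and the cofactor Ncoa6 rose from 113 ± 3.04 to 151 ± 4.56 CPM. Paxip1 was lower (log2 fold change -0.14, adjusted p = 0.0446), a call that was lost without any one of 9 libraries, at an adjusted p of up to 0.152 without hypoxia 2, and Dpy30 was higher (log2 fold change 0.14). The catalytic subunits Kmt2a, Kmt2b, Kmt2c, Kmt2d and Setd1a did not pass the threshold, with log2 fold changes of 0.05, -0.08, 0.01, 0.08 and -0.01 and adjusted p-values of 0.482, 0.383, 0.903, 0.496 and 0.955.

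Clock genes were higher for 10 of 16 members and lower for 1, also when adjusted over the list alone, with a median log2 fold change of 0.26 (camera adjusted p = 1.28e-13, and adjusted p = 0.00506 with an estimated correlation). The repressor Nfil3 rose from 16.5 ± 0.984 to 34.3 ± 2.11 CPM, Nr1d1, which encodes REV-ERB alpha, from 24.9 ± 2.30 to 40.7 ± 1.62 CPM, and Per2 from 18.2 ± 0.528 to 28.0 ± 2.82 CPM. Clock was the member that fell (log2 fold change -0.13).

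Among genes of cholesterol synthesis and uptake, 16 of 25 were higher and none lower (17 and 1 when adjusted over the list alone), with a median log2 fold change of 0.17. The camera adjusted p was 3.95e-08, and this call was lost when the correlation was estimated (adjusted p = 0.249 with an estimated correlation). Insig1, which retains the sterol sensor SCAP in the ER, rose from 140 ± 8.98 to 189 ± 6.90 CPM, Cyp51 from 384 ± 14.9 to 478 ± 17.0 CPM and Lss from 255 ± 16.5 to 325 ± 16.5 CPM, both of them enzymes of sterol synthesis. Hmgcs1, another of them, had a log2 fold change of -0.01.

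**Figure D2:**
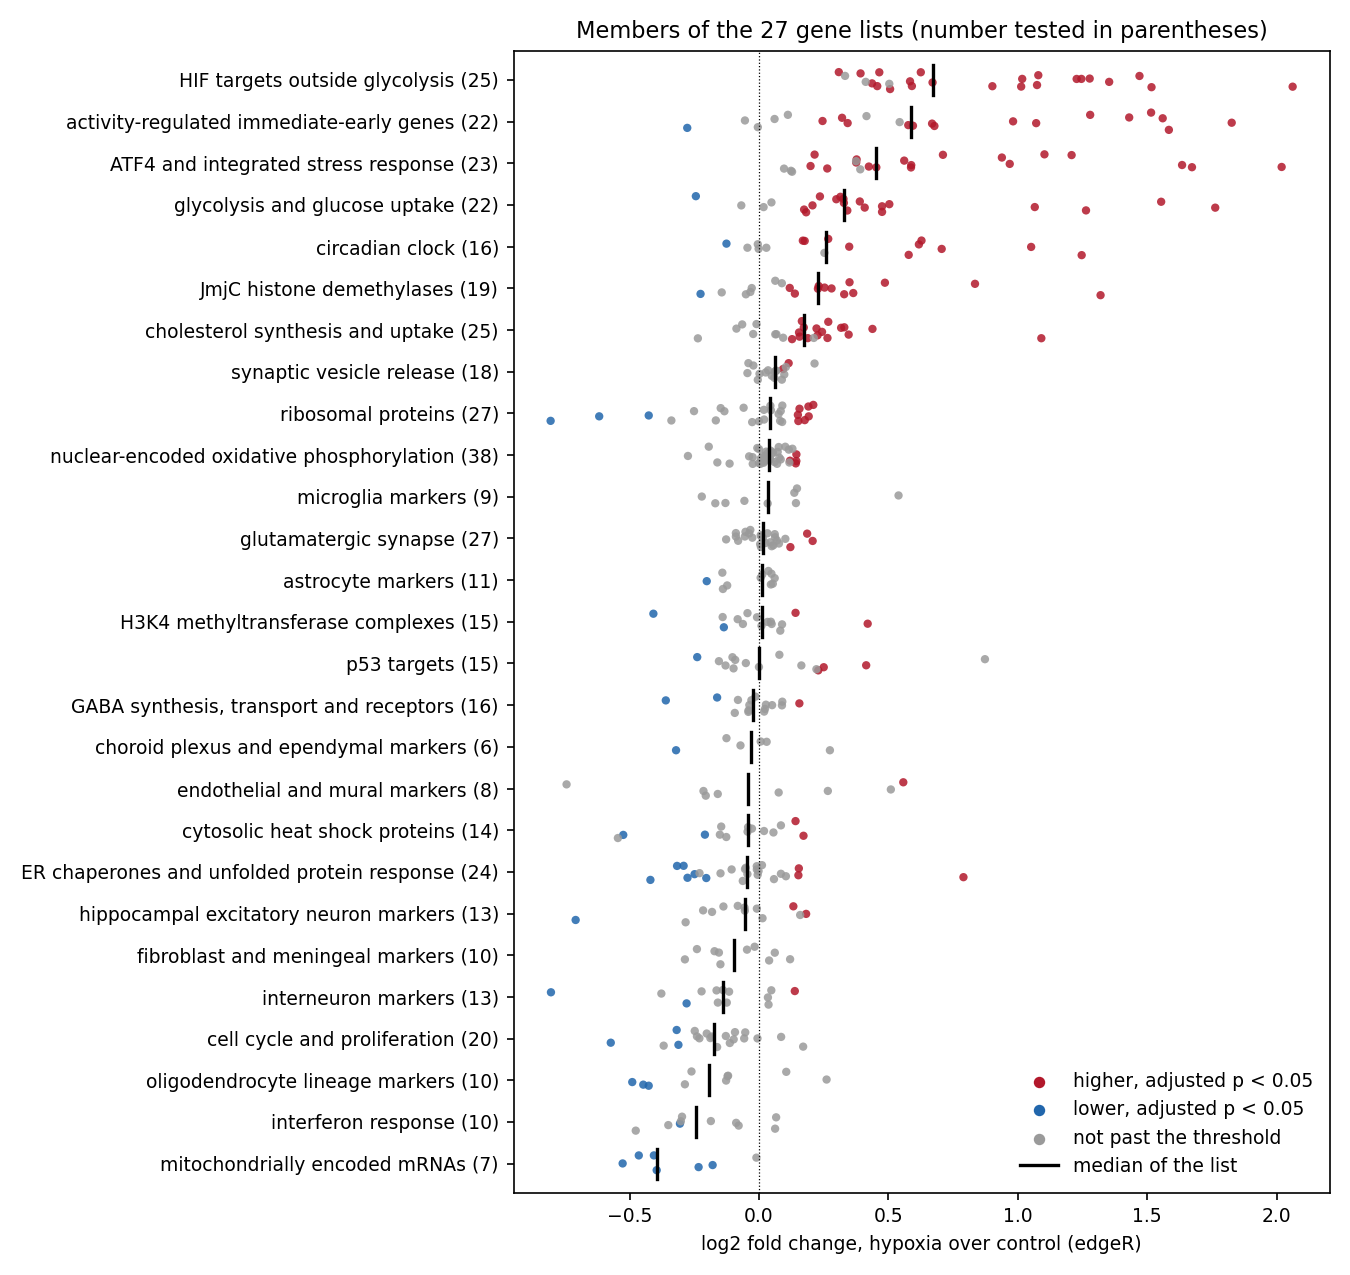
Log2 fold change of each tested member (points) of the 27 gene lists, with black bars at the median of each list and color for members past an adjusted p of 0.05. Medians reach 0.67 for HIF targets and -0.39 for mitochondrially encoded mRNAs, and the medians of the synaptic lists lie close to 0.

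Most of the mitochondrially encoded mRNAs that were measured were lower. Of 13 listed, 7 were measured, and 6 of these were lower, also when adjusted over the list alone. The median log2 fold change was -0.39. The camera adjusted p was 4.54e-06, and this call was lost when the correlation was estimated (adjusted p = 0.249 with an estimated correlation). mt-Nd5 fell from 4157 ± 105 to 2886 ± 266 CPM, mt-Nd1 from 4552 ± 364 to 3436 ± 310 CPM and mt-Nd6 from 1346 ± 86.0 to 1024 ± 110 CPM, all of them subunits of complex I. mt-Nd2, mt-Nd4 and mt-Cytb also fell, with log2 fold changes of -0.46, -0.23 and -0.18, and mt-Co1, a subunit of complex IV, had a log2 fold change of -0.01 (adjusted p = 0.898). With a per-library GC correction the call of mt-Cytb was lost (adjusted p = 0.153). The measured mitochondrial mRNAs made up 3.19 ± 0.154% of counts in control and 2.67 ± 0.169% in hypoxia (exact permutation p = 0.00216, the smallest the 462 splits allow, and 0.00938 adjusted over 13 library measures). The share of mitochondrial rRNA did not pass the threshold (0.406 ± 0.156% and 0.384 ± 0.00896%, exact permutation p = 0.952). The control mean of that share was raised by control 2 at 0.708%, with the other controls at 0.308 to 0.441%, so the direction of its difference depends on this library. Of the nuclear-encoded oxidative phosphorylation genes, 4 of 38 were higher (3 when adjusted over the list alone) and none lower, and the list was not called (camera adjusted p = 0.1098), although its adjusted p was 0.0310 without control 5 and 0.0371 without hypoxia 2. They were Uqcrc2, Sdhd, Ndufs3 and Atp5c1, each higher by less than 25%, and the Atp5c1 call was lost without hypoxia 4 (adjusted p = 0.0512).

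**Figure D3:**
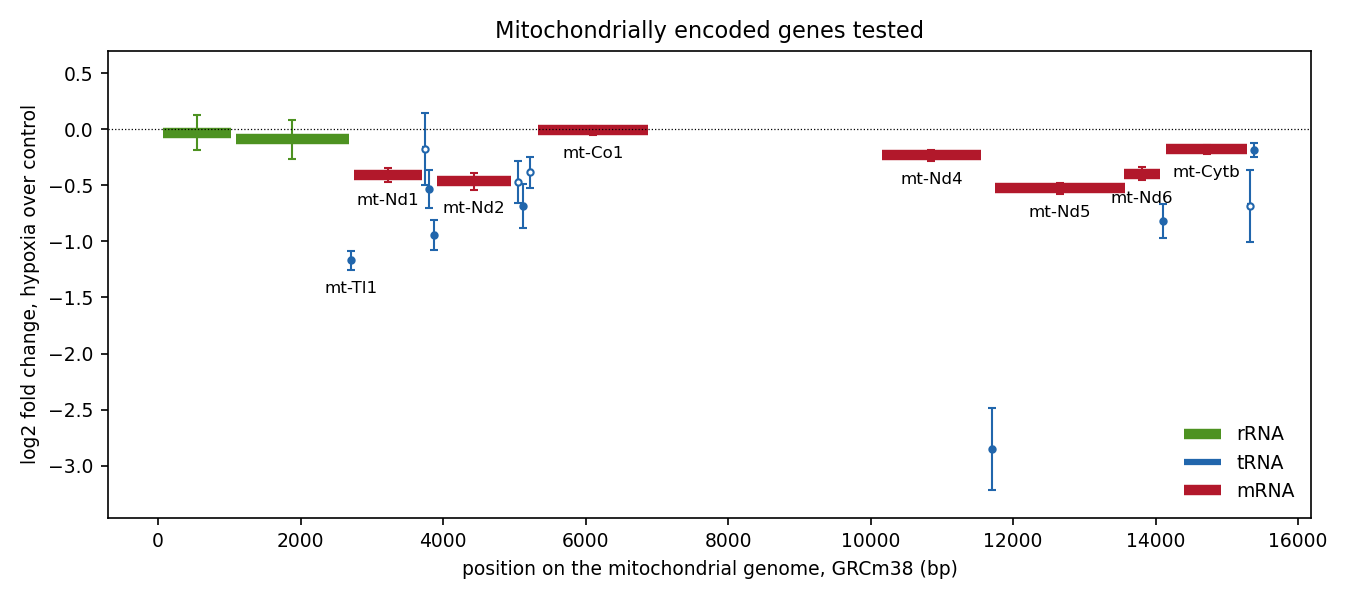
Log2 fold change of each tested mitochondrially encoded gene (bars span the gene or, for tRNA genes, points mark its middle, whiskers show the SE) along the mitochondrial genome in bp, with open points for tRNA genes that did not pass an adjusted p of 0.05. mt-Nd5 lies at -0.53 and mt-Co1 at -0.01.

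Synaptic gene lists were not called. Of 27 glutamatergic synapse genes, 3 were higher (also when adjusted over the list alone) and none lower (median log2 fold change 0.02, camera adjusted p = 0.432): the adhesion protein Nlgn1 rose from 206 ± 5.85 to 238 ± 15.6 CPM, the NMDA receptor subunit Grin2b from 1154 ± 79.6 to 1314 ± 73.5 CPM, and the scaffold Dlg2 1.09-fold. Of 18 synaptic vesicle genes, Syn1 and Syn2, which encode synapsins, were higher by less than 25%, and neither was called when adjusted over the list alone (camera adjusted p = 0.141). Of 16 genes of GABA signalling, 1 was higher and 2 were lower, also when adjusted over the list alone (camera adjusted p = 0.812); the higher one was Gabrb2, which rose 1.11-fold. The calls of Dlg2, Syn1 and Syn2 were lost without some single libraries, at adjusted p-values of up to 0.0682 without hypoxia 3, 0.0632 without hypoxia 1 and 0.0859 without hypoxia 4.

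The lists of other stress responses and of ribosomal proteins were not called. Of 14 cytosolic heat shock genes, 2 were higher and 2 lower (3 and 5 when adjusted over the list alone, camera adjusted p = 0.735): Hsp90aa1 and Hsp90ab1 rose 1.13-fold and 1.10-fold, Hspa8 fell (log2 fold change -0.21), and Hspa1b, which shares reads with Hspa1a, was lower at 6.29 ± 0.763 CPM in control and 4.30 ± 1.24 CPM in hypoxia, a call lost without hypoxia 2 (adjusted p = 0.0523). Of 15 p53 targets, 3 were higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 0.394). The cell cycle inhibitor Cdkn1a rose from 35.6 ± 1.76 to 47.4 ± 4.87 CPM and the p53 ligase Mdm2 from 38.0 ± 2.22 to 45.2 ± 3.57 CPM, Pmaip1 was higher (log2 fold change 0.23), and Sesn1 fell (-0.24). Of 27 ribosomal protein genes, 7 were higher and 3 lower (8 and 4 when adjusted over the list alone, camera adjusted p = 0.450), with a median log2 fold change of 0.04 and a mean of -0.04. Rpl32 and Rpl4 rose 1.16-fold and 1.11-fold, whereas the lower members Rps18, Rpl5 and Rpl27 had low counts and are uncertain. Of 10 interferon response genes, Irf9 was lower (log2 fold change -0.31), also when adjusted over the list alone (camera adjusted p = 0.403, with a list median of -0.24).

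Markers of cell types were compared as measures of what the cultures held. Of 13 excitatory neuron markers, 2 were higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 0.684). The transcription factor Neurod1 fell from 79.6 ± 7.96 to 48.8 ± 5.39 CPM, Tbr1 rose 1.13-fold, and Neurod6 rose 1.10-fold, a call lost without hypoxia 4 (adjusted p = 0.0538). Of 13 interneuron markers, 1 was higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 0.450): Dlx5 fell from 2.10 ± 0.274 to 1.22 ± 0.386 CPM, Dlx1 from 24.6 ± 1.96 to 20.2 ± 1.42 CPM, and Lhx6 rose 1.10-fold, a call lost without any one of 6 libraries, at an adjusted p of up to 0.0798 without control 2. Astrocyte transcripts were abundant, with Gfap at 623 ± 50.0 CPM in control, so a difference between these libraries cannot be assigned to neurons alone. Of 11 astrocyte markers, Aqp4 was lower (132 ± 12.4 and 115 ± 7.78 CPM), but not when adjusted over the list alone, a call lost without any one of 7 libraries at an adjusted p of up to 0.0774 without hypoxia 1 (camera adjusted p = 0.735, with a median of 0.01 and a mean of -0.03).

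Of 10 oligodendrocyte lineage markers, 3 were lower, also when adjusted over the list alone (camera adjusted p = 0.190, and 0.0451 without control 6): Olig1 fell from 54.0 ± 9.21 to 40.4 ± 3.23 CPM, Mog from 5.12 ± 0.660 to 3.62 ± 0.158 CPM, and Olig2 was at 18.2 ± 4.55 and 13.3 ± 2.14 CPM, a call lost without any one of 8 libraries at an adjusted p of up to 0.113 without hypoxia 1. None of 9 microglia markers or 10 fibroblast and meningeal markers passed the threshold (camera adjusted p = 0.735 for both), and of the latter Col3a1 had a log2 fold change of 0.12. Of 8 endothelial and mural markers, the receptor Pdgfrb was higher (14.5 ± 1.35 and 21.4 ± 3.39 CPM), also when adjusted over the list alone (camera adjusted p = 0.735, with a median of -0.04 and a mean of 0.01). Of 6 choroid plexus and ependymal markers, Foxj1 was lower (log2 fold change -0.32), also when adjusted over the list alone (camera adjusted p = 0.766). Of 20 cell cycle genes, 3 were lower, 2 when adjusted over the list alone (median log2 fold change -0.17, camera adjusted p = 0.0649). They were Plk1 (log2 fold change -0.57), Ccna2 (-0.31) and Birc5 (-0.32), and without some single libraries the calls of the latter pair were lost, at adjusted p-values of up to 0.0634 without hypoxia 2 and 0.115 without hypoxia 1. The call of the list changed without some libraries: its adjusted p was 0.0180 without control 3, 0.0127 without control 6, 0.0371 without hypoxia 2 and 0.0186 without hypoxia 3.

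The authors' deposited tables list 2099 higher and 1693 lower genes, so that 55.4% of their calls were higher against 44.2% here. This share depends on the scaling, the test and single libraries: here it was 49.9% with RLE factors, 52.9% with DESeq2, 38.4% with library totals only, 50.8% with the GC correction, 50.8% without control 1 (2081 higher and 2018 lower) and 49.8% without hypoxia 2. Of their genes, 1567 were also called higher here and 1598 lower, and none in the opposite direction. Across the 3790 of their 3792 genes tested here, the log2 fold changes had a Pearson r of 0.999 and a Spearman rho of 0.998 across genes, and all had the same sign; both sets come from the same libraries and are not independent. Prelid2 and Cfap53, higher in the authors' deposited table with log2 fold changes of 1.48 and 1.29, were not tested here because of low counts. In the authors' deposited table Adm had a log2 fold change of 2.17 and Txnip of -2.16. A further 557 genes were called here and are not in those tables, 304 of them not protein-coding.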

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

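The test of whether control RNA mixed into hypoxia 5 explains its values and the split of its response by direction were chosen after the result was seen, and the other tests here were set before their results were seen. Within each group of libraries, 196 sets of values were searched for a single library far from the rest, measured by its gap to the nearest other library relative to the whole range. Of these sets 21 had such a library, and chance alone gives about 1 in 20. Gene levels in CPM made up most of the sets but held only 9 of the 21, about as many as chance gives. The others were total counts and shares of gene classes, which are not independent of each other. For Txnip and Kdm3a the search alone therefore does not argue against chance.

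Txnip stood at 9.54 CPM in hypoxia 5 and at 5.05 to 5.27 CPM in the other hypoxia libraries, and Kdm3a at 159 CPM in hypoxia 5 and 193 to 204 CPM in the others. Fitted on the fold changes of the other hypoxia libraries over 568 genes, the response of hypoxia 5 had a slope of 0.703, below the slopes of 0.800 to 0.904 of the other 4 libraries, which is what a smaller response would give. The genes were chosen anew for each library from a fit without it, 471 to 511 for the other 4, so slopes and correlations cover different genes. The slope of hypoxia 5 was the lowest in both directions, clearly over higher genes (0.650 against 0.856 to 1.02) and slightly over lower genes (0.750 against 0.756 to 0.815). The reduction was not shared by all higher genes. Adm, Hk2, Bhlhe40 and P4ha1 were highest among the hypoxia libraries in hypoxia 5 (13.0, 99.8, 74.4 and 182 CPM), whereas Npas4 was lowest there (8.43 CPM). The slope therefore cannot settle whether a smaller response accounts for Kdm3a, which is among the higher genes. Over lower genes the reduction was too small to account for the whole gap of Txnip. A GC bias of the library as the whole cause was argued against, because Txnip in hypoxia 5 stayed 0.90 above the others in log2 CPM after the per-library GC correction (0.88 before). Control RNA mixed into hypoxia 5 was also argued against: Txnip would need 19.1% of control RNA, which would lower the slope over genes lower in hypoxia to 0.635, below the 0.750 observed (mean of the other 4 libraries 0.785, SD 0.0263). The fold changes of hypoxia 5 also correlated less with those of the other hypoxia libraries (Pearson r across genes 0.796, against 0.907 to 0.936). Why its slope was lower, mostly over higher genes, stays open, and no biological explanation was tested.

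The same library had the lowest shares of lincRNA (0.513% of counts, 0.681 to 0.732% in the other hypoxia libraries), of genes annotated as TEC (0.0646% against 0.0889 to 0.0939%) and of processed transcripts (0.193% against 0.211 to 0.214%).

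Control 1 had the smallest total, 1.66e+07 counts against 2.67e+07 to 3.14e+07 in the other controls, and a mitochondrial tRNA share of 0.0128% against 0.00985 to 0.0103%. Its CPM also stood apart for AW047730 (8.01 CPM, 5.20 to 6.19 in the others), Paxip1 (35.0 CPM, 38.3 to 39.9), Dlg2 (615.1 CPM, 545 to 562) and Atp5c1 (212 CPM, 189 to 194).

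In control 2 the share of protein-coding counts was 96.9% (97.8 to 98.2% in the other controls), of antisense genes 0.239% (0.145 to 0.175%), of mitochondrial rRNA 0.708% (0.308 to 0.441%), of rRNA 0.576% (0.0532 to 0.0758%) and of miRNA genes 0.0458% (0.00589 to 0.00878%). Of 7 genes for rRNA and mitochondrial rRNA, 5 were highest among the controls in this library, and Mir6236 had 11365 counts there and 991 to 2226 in all other libraries. In hypoxia 1 rRNA made up 0.142% of counts (0.0738 to 0.0902% in the other hypoxia libraries), miRNA genes 0.0123% (0.00546 to 0.00716%), and Insig1 stood at 177 CPM (191.5 to 194). Most of both raised miRNA shares came from Mir6236. Without it the share was 0.00330% in control 2 (0.00232 to 0.00282% in the other controls). In hypoxia 1 it was 0.00245% (0.00186 to 0.00242% in the other hypoxia libraries). Chac1 stood at 8.40 CPM in control 4 (6.55 to 6.79 in the other controls), and Rpl4 at 399.6 CPM in control 6 (419 to 429).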

How the results depend on the processing

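The GC correction, the covariate for the leading axis within groups, and the fit without control 1, control 2 and hypoxia 5 were chosen after the data were seen, and all other alternatives before. No gene called in the comparison had the opposite sign under any of the 23 other settings, and no result reversed. The number of higher genes ran from 1297 to 2397 and of lower genes from 1500 to 2754. Higher and lower calls numbered 2053 and 1827 with DESeq2, 2397 and 2323 with the GC correction, 2245 and 2754 with the axis covariate, and 2331 and 2370 without the 3 libraries. Leaving out 1 library gave 1385 (hypoxia 3) to 2081 (control 1) higher and 1500 (hypoxia 2) to 2042 (hypoxia 5) lower genes. With the replicate number as a block, 1297 genes were higher and 1649 lower. Libraries with the same number had correlations of their deviations of -0.42, 0.29, -0.15, -0.23 and 0.37 for numbers 1 to 5, and 2 of 5 controls correlated best with their own number, so the numbers were not taken to pair libraries. The causes of the following changes were not tested. The synaptic vesicle list passed without a filter on low counts (adjusted p = 0.0126) and with limma-voom (0.0322), as did oxidative phosphorylation (0.00808 and 0.0254) and the cell cycle list (0.00416 and 0.0345), the last also with the replicate block (0.0153) and the GC correction (0.0458). Without 1 library the adjusted p was 0.0310 to 0.338 for oxidative phosphorylation (under 0.05 without control 5 or hypoxia 2), 0.0127 to 0.285 for the cell cycle (without control 3, control 6, hypoxia 2 or hypoxia 3) and 0.0451 to 0.338 for oligodendrocyte markers (without control 6). With an estimated correlation 5 lists were called, and glycolysis (adjusted p = 0.229), mitochondrial mRNAs (0.249) and cholesterol synthesis (0.249) were not. By fry, which does not compare with other genes, p53 targets (0.0241, up) and interferon genes (0.0170, down) passed. So did glycolysis (0.00275, up), mitochondrial mRNAs (0.00187, down) and cholesterol synthesis (0.00187, up). At an adjusted p under 0.01 in both, the overlap with the authors' tables was 926 higher and 912 lower genes, as a stricter threshold calls fewer genes. Of 88 genes that the rule names 79 were called, 13 of these lost the call without some 1 library and 12 in another setting, and Hif1a and Kmt2a gained one. Some small changes are missed: in simulated data 64.2% of changes by 25% were called.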

Other observations

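The tests of low abundance for lincRNA and other noncoding genes and of a shared decrease of mitochondrial mRNAs were chosen after the results were seen, as were the 5 gene lists described next. Because these lists were chosen after values of their members had been seen, they are described by their members and not tested as groups.

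Genes of glycogen metabolism were higher for 6 of 23 members and lower for 1 (6 and 2 when adjusted over the list alone). Glycogen synthase 1 (Gys1) rose from 35.7 ± 7.40 to 71.7 ± 3.92 CPM, and the glycogen-targeting phosphatase subunits Ppp1r3b, Ppp1r3c and Ppp1r3g rose 3.17-fold, 2.37-fold and 1.83-fold. Gbe1 and Epm2a were also higher, and the glycogen phosphorylase Pygm was lower (log2 fold change -0.42). Ppp1r3c is also in the list of HIF targets. Cytosolic aminoacyl-tRNA synthetases were higher for 13 of 20 and lower for none (14 and 0 when adjusted over the list alone), led by Iars, which rose from 95.1 ± 3.46 to 135 ± 3.07 CPM. MAP kinase phosphatases and Sprouty proteins were higher for 8 of 15 and lower for none (9 and 0 when adjusted over the list alone). The strongest of them, Dusp1, is also in the list of immediate-early genes; Dusp16 rose 1.84-fold and Dusp8 1.33-fold.

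Of 13 genes of microRNA processing and Argonaute proteins, 5 were lower and none higher, also when adjusted over the list alone. Dicer1, the enzyme that cleaves microRNA precursors, fell from 110 ± 3.83 to 74.1 ± 3.54 CPM, and Dgcr8, the partner of Drosha, from 36.1 ± 1.62 to 25.2 ± 1.79 CPM. Tarbp2, Tnrc6a and Tnrc6c also fell, with log2 fold changes of -0.39, -0.31 and -0.19, while Drosha had a log2 fold change of 0.04. Of 7 alpha-arrestins and their regulators, Txnip and Arrdc4 were lower and Arrdc3 was higher (log2 fold change 0.84), also when adjusted over the list alone.

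Other splits of the 11 libraries into 6 and 5 were compared with the real one, over 100 splits drawn with the real one included. The real split was the only 1 of the 100 to give 1644 higher genes (highest other 1084) or 2078 lower genes (highest other 1069), which argues against chance. Both of these other counts came from 1 split, which set control 2 to 6 against control 1 and all hypoxia libraries. It thus kept most of the real grouping, and the rest of the splits drawn gave no calls. Chance was also argued against for the 5 lists called with an estimated correlation (1 split, highest other 1). It was not for the 8 lists called with the preset correlation, as 47 splits called as many and the highest other called 14. By list, permutation over these splits excluded chance for HIF targets (camera p = 1.64e-47, smallest other 3.40e-28), JmjC demethylases (2.80e-11 and 9.49e-08), ATF4 targets (7.42e-57 and 2.98e-20), immediate-early genes (2.16e-33 and 2.20e-14) and clock genes (1.90e-14 and 1.04e-07), with 1 split each. Chance was not argued against for glycolysis (8 splits, 3.85e-14 and 8.71e-20), mitochondrial mRNAs (5 splits, 1.35e-06 and 8.56e-09) or cholesterol synthesis (13 splits, 1.03e-08 and 1.03e-14).

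Long intergenic noncoding RNA (lincRNA) genes were lower as a class, with 84 of 434 lower and 13 higher and a median log2 fold change of -0.18, which 1 of the 100 splits reached (lowest other -0.18, so the margin was narrow). Low abundance of the class was argued against as the whole cause, as protein-coding genes matched on mean expression had medians of -0.09 to -0.03 in the central 95% of 1000 draws. It may account for a part, as the middle of these medians was -0.06 and the median of all protein-coding genes -0.01. The matched ranges come from drawing genes and hold no spread between libraries. GC bias between libraries was argued against as the whole cause by a median of -0.17 after the GC correction (matched range -0.08 to -0.02). Fewer reads from coding genes nearby were argued against as the whole cause by a median of -0.15 over the 179 lincRNA genes farther than 5 kb from any (matched range -0.11 to -0.01). Without each library in turn the median ran from -0.21 to -0.14. The decrease was not limited to lincRNA: the medians were -0.17 for 473 antisense genes (60 lower and 11 higher, matched range -0.11 to -0.05), -0.17 for 419 genes annotated as TEC (69 and 16, -0.11 to -0.04) and -0.19 for 261 processed transcripts (49 and 11, -0.10 to -0.03). Processed pseudogenes went the other way (4 lower and 17 higher, median 0.07). As shares of all counts, lincRNA, antisense and TEC genes did not pass the threshold (exact permutation p adjusted over 13 library measures = 0.0619, 0.414 and 0.281), and processed transcripts were lower (0.0141). An effect of low oxygen on noncoding transcripts stays open as a hypothesis that was not tested further.

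The measured mitochondrial mRNAs fell unequally, from a log2 fold change of -0.53 for mt-Nd5 to -0.01 for mt-Co1. A single lower mitochondrial share for all of them was argued against, as the range of their group differences in log2 CPM was 0.52, larger than in any other of the 462 splits (highest other 0.45, exact permutation p = 0.00216, the smallest these allow). GC bias as the whole cause was argued against by a median of -0.29 after the GC correction, although every decrease shrank: mt-Nd4 moved from -0.23 (SE 0.05) to -0.13 (SE 0.04) and kept its call (adjusted p = 0.0336), and mt-Cytb moved from -0.18 (SE 0.04) to -0.07 (SE 0.04) and lost its call because the fold shrank. Unequal loss or synthesis of these mRNAs under low oxygen may account for the range and was not tested. Among the 11 mitochondrial tRNA genes tested 7 were lower and none higher, with a median log2 fold change of -0.68. The libraries were made from polyadenylated RNA, so these counts need not measure mature tRNA. They may in part come from reads of genes beside them: mt-Tl1 (2676 to 2750) lies directly between mt-Rnr2 (to 2675) and mt-Nd1 (from 2751). These neighbours changed less, by -0.09 (SE 0.17) for mt-Rnr2 and -0.41 (SE 0.06) for mt-Nd1, against -1.17 (SE 0.08) for mt-Tl1. Reads in proportion to the levels of both genes would therefore not give its full decrease. Where the tRNA gene counts come from was not tested. Some counts were also low, such as 0.715 CPM for mt-Ti and 0.972 CPM for mt-Tn in control.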
